A study of Oryza sativa with 2 samples.

How the data were processed

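Poly(A) RNA was measured by sequencing in 2 libraries of whole seedlings, 3 weeks old, of the wild-type rice cultivar 93-11, an indica variety. Both libraries belong to the same group, and the labels number them replicate 1 and replicate 2. They do not say whether the replicates came from separate plants or pools, so the spread between them may be partly technical. No treatment, mutant or other cultivar is part of this data set, so there is no contrast between conditions to test. The labels describe hydroponic growth in Yoshida solution under short days, an RNA extraction kit for plants, an NEBNext library kit and sequencing on an Illumina HiSeq X-ten.

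The authors deposited 1 table per library with a locus ID and an FPKM value, per the file headers. FPKM is a fragment count divided by transcript length and by the total number of mapped fragments. TopHat2 and Cufflinks are named, without versions, in the submitters' processing notes. The genome build, the annotation, the counting settings and any filters are not given in the sources used here. The IDs have the form of a rice locus name, with a chromosome code after the letters Os and a locus number after the letter g. This form is that of an annotation of japonica rice, whereas 93-11 is indica, and which genome the reads were aligned to is not given. If it was a japonica genome, loci divergent or absent in 93-11 would also be undetected, which bears on the detected shares of all loci, by chromosome and by position. Both tables list the same 37896 rows in the same order, with 37895 distinct IDs. The ID listed on 2 rows has different values on them, and both rows were kept.

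No fragment counts come with FPKM, so the absolute depth is unknown and no counting interval or detection floor could be given. The relative depth was estimated from 1169 loci between 0.001 and 0.3 FPKM in both libraries. Where 1 or 2 fragments lie behind a value, the ratio of the libraries takes preferred steps. Only similar depths were searched, so a much shallower library could not have been returned. Within this range, the position of the steps put replicate 1 at 1.13 times the depth of replicate 2. At this position 12.0% of the low loci lay within 0.03 (log2) of a step, against 4.11% at the median trial position. The position was picked as the trial with the most such loci, so a share above the median was given in advance. On simulated fragments with 3 known relative depths, the largest error of this estimate was 1.93%. These 3 depths lay within the range searched, and the simulated values had no estimation step. The error on the deposited values is therefore unknown. Values above 0 but under 0.001 FPKM were listed for 93 loci in replicate 1 and 90 in replicate 2; like other values under 1 FPKM, they were treated as not detected. An exact 0 is reported only as listed at 0, since an estimation step can also leave one.

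Gene names were sought in the supplied RefSeq gene table of the Japonica assembly ASM3414082v1, which has 39387 genes. Only 1 of the 37895 IDs matched an entry. The 28 gene lists fixed before the data were examined, which rested on gene names or protein sequences, therefore had no matched member and could not be run. For the same reason the planned summaries by gene length, exon number and GC content were not run. Loci are given by ID, with their chromosome code, and no gene function is stated for them. The rule for the loci to print, also fixed in advance, took the 20 most abundant loci, the 5 with the largest ratio between libraries in each direction among loci with a mean of 10 FPKM or more, the top 4 members of each list, and the highest locus of each chromosome, with at most 2 IDs per part where no name was paired with an ID.

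A locus was called detected at 1 FPKM or more. Agreement was computed across loci on log2(FPKM + 1), leaving out loci listed at 0 in both libraries; loci are not independent replicates and no p-value was attached. Loci were called apart when the libraries differed more than 2-fold on log2(FPKM + 1) after scaling both to the same total, among loci with a mean of 10 FPKM or more. The added 1 understates the ratio of low loci. These calls are descriptive, since 1 library against 1 library has no replicate check. In a simulation for replicate 1 against replicate 2, over 37896 loci with 200 changed 4-fold, 100% of the changed loci were recovered. The simulated spread was set from the median difference between the libraries, so this checks the calculation and not the rate of false calls. Chromosome codes and numbers were read from the IDs. Levels are given as mean ± SD over the 2 libraries.

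The alternatives, fixed before the data were examined unless stated in the closing section, were other pseudocounts, detection thresholds, scalings, level minimums and fold limits, and each library on its own. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.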

Results

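The transcriptome of 93-11 rice seedlings was profiled in 2 libraries of a single wild-type group. The series belongs to a study of adenine methylation in rice DNA and its association with gene expression, and the data described here give the expression levels alone. The tables held 37896 locus rows. The FPKM values summed to 741624 in replicate 1 and 668305 in replicate 2, and the median locus stood at 1.77 and 2.09 FPKM. The number of sequenced fragments is unknown. In a search limited to similar depths, the steps between low values put replicate 1 at 1.13 times the depth of replicate 2. With 1 group the question that the data answer is which loci the seedlings expressed, at what level, and how far the replicates differed.

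Transcripts of 53.1% of the listed loci were detected in both seedling libraries. At 1 FPKM or more, 20128 loci were detected in both libraries, 2147 in only 1 of them and 15621 in neither. Each library alone gave 20897 loci (replicate 1) and 21506 loci (replicate 2). The median level of the loci detected in both was 10.4 FPKM. A mean of 10 FPKM or more was reached by 10366 loci, 100 FPKM by 998 loci and 1000 FPKM by 59 loci. A further 9926 loci (26.2%) were listed at 0 in both libraries and 1988 in only 1. Without fragment counts, a locus listed at 0 cannot be told from one below the detection limit, nor, with IDs in the form of a japonica annotation, from one that is divergent or absent in 93-11.

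A small number of loci held much of the summed FPKM. The 10 most abundant loci took 10.6% ± 1.76 of the sum (SD, n = 2), the 100 most abundant 29.4% ± 4.25 and the 1000 most abundant 55.1% ± 2.86. The most abundant locus by the mean of the 2 libraries, LOC_Os01g10400 on chromosome 1, stood at 11488 ± 1954 FPKM (SD, n = 2). The next by mean, LOC_Os09g01000 on chromosome 9, stood at 10284 ± 5589 FPKM, with 14236 FPKM in replicate 1 and 6331 FPKM in replicate 2. In replicate 1 alone LOC_Os09g01000 was the highest locus. In replicate 2 LOC_Os01g10400 was the highest, and further loci lay above LOC_Os09g01000. The 20 most abundant loci ranged from a mean of 2745 FPKM to 11488 FPKM and lay on 10 chromosomes. Of these, 19 were higher in replicate 1 as deposited, and 18 remained so after the libraries were scaled to the same total.

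Only 1 locus could be paired with a gene name. LOC_Os01g19850 is OsCCC2, also called KCC2, a member of the cation-chloride cotransporter family. It stood at 0.406 ± 0.0700 FPKM (SD, n = 2), with 0.357 FPKM in replicate 1 and 0.456 FPKM in replicate 2. It was below the detection level in both libraries, and its mean lay at the 36.3 percentile of all loci. This gene was named because it was the only match, not by its value.

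The levels of the loci followed each other closely between the replicates. Across the 27970 loci above 0 in at least 1 library, Pearson's r of log2(FPKM + 1) was 0.950 and Spearman's rho was 0.941. Sorted by mean level into 10 groups of 2797 loci, the closest agreement among those above 1 FPKM was in the eighth group, at a median level of 16.7 FPKM. There the median difference of FPKM + 1, as deposited, was 1.16-fold and 90% of loci differed less than 1.64-fold. In the fourth group, at a median level of 2.48 FPKM, these values were 1.25-fold and 2.14-fold. The added 1 makes them smaller than the folds of FPKM itself, most so at low levels. In the top group, at a median level of 75.2 FPKM, they were 1.24-fold and 1.73-fold. A difference of 2-fold at a single locus of low level was therefore within the range that replicates of the same group gave.

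The loci that differed most between the replicates were mainly higher in replicate 2. Among the 10366 loci with a mean of 10 FPKM or more, 676 (6.52%) differed more than 2-fold after scaling to the same total, 543 of them higher in replicate 2 and 133 higher in replicate 1. As deposited, without scaling, the numbers were 450 and 198, so the share higher in replicate 2 was 80.3% with scaling and 69.4% without. Scaling to the same total shifted the log2 ratio of replicate 1 over replicate 2 by -0.15, and scaling by the median of ratios by -0.06. Differences of more than 8-fold were found at 104 loci in favour of replicate 2 and at 4 in favour of replicate 1. The largest was at LOC_Os01g14850 on chromosome 1, with 0.121 FPKM in replicate 1 and 913.8 FPKM in replicate 2. LOC_Os01g60740, also on chromosome 1, had 0.291 FPKM in replicate 1 and 540.5 FPKM in replicate 2. In the other direction, LOC_Os04g43820 on chromosome 4 had 47.1 FPKM in replicate 1 and was listed at 0 in replicate 2. LOC_Os01g09214 on chromosome 1 had 134.8 FPKM in replicate 1 and 12.8 FPKM in replicate 2. A group of 99 loci on 12 chromosomes was under 1 FPKM in replicate 1 and at 10 FPKM or more in replicate 2, against 6 loci with the reverse pattern. Those 99 loci had a median of 21.2 FPKM in replicate 2 and held 0.792% of its summed FPKM. With 1 library on each side, these differences have no replicate check.

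**Figure D1:**
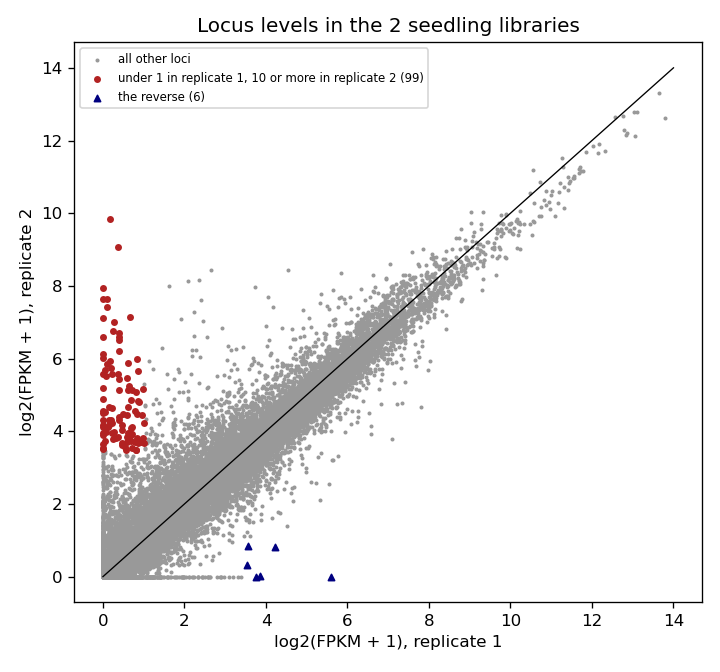
Each point is a locus, with log2(FPKM + 1) of replicate 1 on the x axis and of replicate 2 on the y axis; the line marks equal values. The 99 loci under 1 FPKM in replicate 1 and at 10 FPKM or more in replicate 2 are red circles and the 6 loci of the reverse pattern are blue triangles, while most other loci lie along the line and 54 of the 59 loci with a mean of 1000 FPKM or more lie below it.

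The detected share of loci differed between the highest and lowest chromosomes by more than between the replicates. Chromosome 3 had the highest share of loci at 1 FPKM or more, 63.2% ± 1.72 (SD, n = 2) of 4358 loci. Chromosomes 2 and 1 followed, with 60.6% ± 1.36 of 4150 loci and 60.5% ± 1.03 of 5009 loci. The order of chromosomes 1 and 2 changed with the replicate. Chromosome 11 had the lowest, 45.1% ± 0.926 of 2519 loci, and chromosome 10 the next lowest, 50.3% ± 0.912 of 2248 loci. Chromosome 11 also had the lowest median level among loci detected in both libraries, 7.30 ± 0.154 FPKM, and chromosome 3 the highest, 12.01 ± 0.0684 FPKM. The share was higher in replicate 2 on each of the 12 chromosomes. Chromosome 1, with 5009 of the 37896 rows, held 14.9% ± 0.114 of the summed FPKM. Chromosome 10, with 2248 rows, held 4.64% ± 0.124. These shares are not adjusted for the number of loci. The most abundant locus of each chromosome ranged from a mean of 1749 FPKM on chromosome 4 to 11488 FPKM on chromosome 1. Loci whose IDs carry the codes 13, 14 or xx in place of a chromosome from 1 to 12 numbered 143, and 24 of them (16.8%) were detected in both libraries. What these codes stand for is not given in the sources used here.

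**Figure D2:**
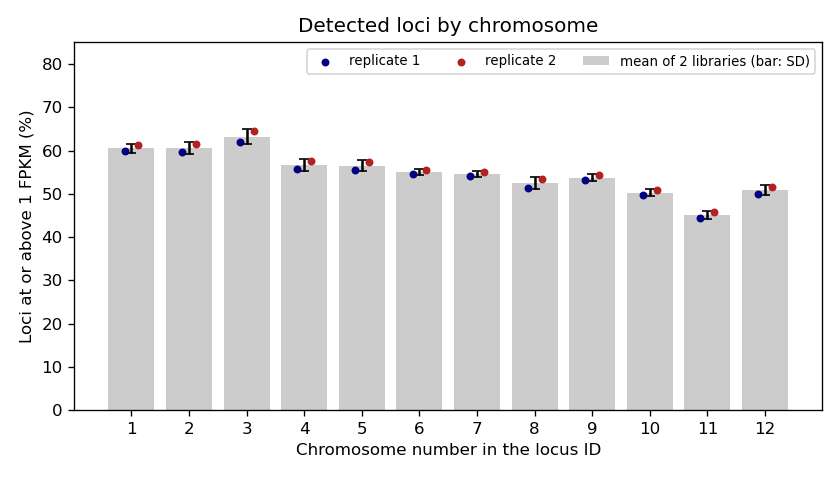
Bars show the mean percentage of loci at or above 1 FPKM for each chromosome number in the locus ID, error bars the SD of the 2 libraries, and points each library. The share runs from 45.1% on chromosome 11 to 63.2% on chromosome 3, and replicate 2 lies above replicate 1 on each chromosome.

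Along the chromosomes, cut into 10 equal parts of the locus number range, the detected share was on average lowest in the fourth part and highest in the last. This division was chosen after the data were seen, and locus numbers give an order of names and not a distance in bases. The share of loci detected in both libraries was 53.3% ± 10.1 in the first part (SD over 12 chromosomes), 39.7% ± 7.11 in the fourth and 60.7% ± 7.76 in the last. Single chromosomes differed from this average. On chromosome 10, 32.3% of 229 loci were detected in the first part and 31.1% of 222 loci in the fifth, against 67.6% of 281 loci in the last. Chromosome 4 had 33.6% in its second part, and chromosome 9 was lowest in its second part, at 34.6%. Chromosome 11 was highest in its first part, at 52.9%, with 42.7% in the last.

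**Figure D3:**
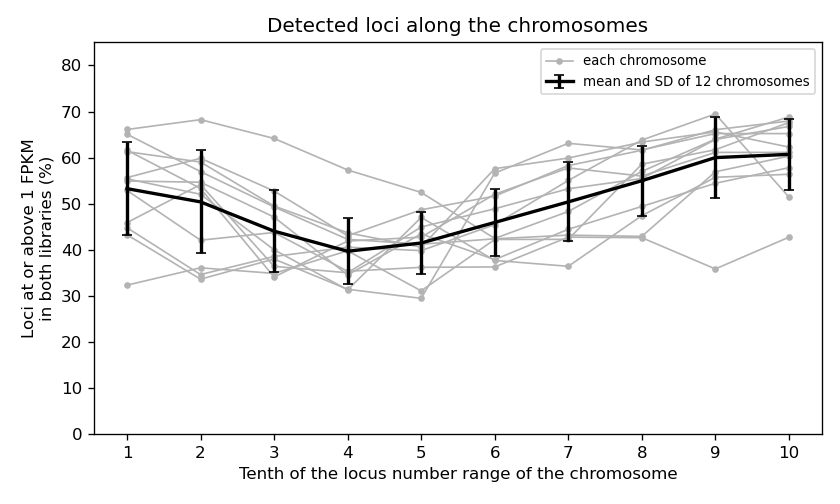
Grey lines show, for each of 12 chromosomes, the percentage of loci at or above 1 FPKM in both libraries in 10 equal parts of the chromosome's locus number range; the black line and bars show the mean and SD over chromosomes. The mean falls from 53.3% in the first part to 39.7% in the fourth and reaches 60.7% in the last.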

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

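The settings below were chosen before the data were examined unless said otherwise. No paired analysis was possible because there is only 1 group of samples. Detected loci in both libraries stayed within 1.5 times of 20128 under each threshold, rescaling and single library tried. Ranked in 1 library alone, the top 10 loci held 9.31% to 11.8% of the sum and the top 100 loci 26.7% to 32.6%. Pearson's r was 0.926 with a pseudocount of 0.1, 0.871 with 0.01, 0.967 with all loci kept and 0.922 with loci at 1 FPKM or more in either library; Spearman's rho was 0.963 with all loci kept and 0.919 with loci at 1 FPKM or more in either library. The loci apart between replicates, higher in replicate 1 and in replicate 2, numbered 360 and 1560 with a mean of 1 FPKM or more, 42 and 108 with a mean of 50 FPKM or more, 484 and 1216 at 1.5-fold, and 22 and 181 at 4-fold. Scaling by the median of ratios gave 175 and 490, and 3 further settings were chosen after seeing the data: a total without the 100 most abundant loci gave 186 and 470, a pseudocount of 0.1 gave 148 and 579, and leaving out the loci near 0 in 1 library gave 132 and 490. More loci were higher in replicate 2 under each of these settings. The difference between chromosomes 3 and 11 in the share of loci detected in both libraries was 18.3 percentage points, with 14.5 at a threshold of 0.1 FPKM, 19.6 at 5 FPKM, 20.2 with locus numbers ending in 0 only (chosen after seeing the data), and 17.6 to 18.7 for the share detected in 1 library alone. The settings foreseen for gene lists, gene structure and fragment shares by transcript length were not run, since the IDs could not be matched to names or lengths. Unknown fragment counts limit what can be said of loci under 1 FPKM.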

Other observations

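The tests on locus numbers ending in 0 and on sums with the next loci were set before their results were seen; the other tests below were chosen after the patterns were seen. Locus numbers that end in 0 made up 31895 of the rows, and 54.8% of them were detected in both libraries. Of the 6001 loci whose numbers end in another digit, 44.1% were detected in both. Their median was 0.834 FPKM in replicate 1 and 0.909 FPKM in replicate 2, against 2.13 and 2.52 FPKM for numbers ending in 0. The share listed at 0 in both libraries was 25.6% and 26.3%. Loci next to each other in number had more similar levels than loci shuffled within chromosomes. The rank correlation over 37741 neighbouring pairs was 0.166 in replicate 1 and 0.169 in replicate 2, and the highest of 1000 shuffles was 0.0265 and 0.0268. The shuffles also removed differences between broad parts of a chromosome. The comparison therefore cannot tell likeness of adjacent loci from such broad differences.

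The 99 loci under 1 FPKM in replicate 1 and at 10 FPKM or more in replicate 2 included 5 loci in a short stretch of chromosome 10, from LOC_Os10g05950 (0.0755 and 198.1 FPKM) to LOC_Os10g06000 (0.0645 and 170.5 FPKM), singled out after their values were seen. Failed estimates are argued against for most of the 99 loci, since 80.8% of them stood at 0.001 FPKM or more in replicate 1. For the remaining loci, 16 of them listed at 0 in replicate 1, failed estimates stay open. A much lower depth of replicate 1 is argued against for the set as a whole. Loci listed at 0 numbered 11021 in replicate 1 and 10819 in replicate 2, and a much shallower library would list many more. Loci at 1 FPKM or more numbered 20897 and 21506. Most of the 99 loci also kept low values above 0 in replicate 1, and FPKM is already divided by the mapped total. The relative depth of 1.13 cannot decide this, since its search was limited to similar depths and could not have returned a much lower value. Fragments given to a next locus in replicate 1 stay open. The sum with the next loci still differed over 4-fold at 43.4% of the loci, short of the 50% set beforehand to argue against this. In a measure added later, 5 loci (5.05%) had a next locus higher in replicate 1 by at least 50% of the missing value. A next locus higher in replicate 2 by as much was found for 13 loci. Both measures leave locus lengths out of account. An abundant next locus can also bring the sum under 4-fold by itself, so the sum cannot decide. A difference in plant material or stage between the samples may also be the source and stays open, since the IDs carry no gene names. Of the set, 6 loci had another member as the next locus, 4 of them in that stretch and 2 elsewhere. Random sets of like level had a median of 0, and 45 of 10000 had as many as 6. Most of the 6 lie in the stretch singled out from these same values, so the comparison cannot decide on the source.

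The 59 loci with a mean of 1000 FPKM or more were higher in replicate 1, by a median log2 ratio of 0.54 as deposited, and 54 of the 59 had this direction. The scaling of the libraries is argued against as the whole cause, since the median was 0.48 after scaling by the median of ratios and 0.39 after scaling to the same total, where 52 of the 59 were higher in replicate 1. No biological explanation was tested.

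As a hypothesis, loci near the chromosome ends may be detected more often than those in the middle; the contrast was built from the profile that prompted it, so no p-value is given. The share detected in both libraries was 56.9% in the outer 20% of the locus numbers at both ends pooled and 44.1% in the middle 20%, a difference of 12.8 ± 3.27 percentage points (SD over 12 chromosomes). The high-numbered end lay above the middle on 12 of 12 chromosomes, by 16.1 ± 5.73 percentage points, and the low-numbered end on 9, by 7.82 ± 8.67 over all 12, being below the middle on chromosomes 4, 9 and 10. Loci with numbers not ending in 0 are argued against as the source of the pooled difference, which was 14.4 percentage points without them. The median level of detected loci was higher at the ends on 7 of 12 chromosomes, and which kinds of loci the middle holds could not be examined without names.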
